A study of Mus musculus with 16 samples.

How the data were processed

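The mice were 70 days old and gender-matched. RNA of isolated colonic epithelial cells with an integrity number of at least 8.5 per the labels was pooled from 3 mice for each array, with 2 arrays in each of 8 groups. The labels give the replicates as separate pools of separate mice, name no hybridisation batch or date, and do not say which mice were littermates. The deposited values are log2 intensities from an Affymetrix whole-transcript array, made with RMA (background correction, quantile normalization and probe summary) per the submitters' processing notes. The version of RMA is not given in the sources used here. They were tested on the table itself: 35557 probe sets in 16 columns, running from 1.857 to 14.938, with medians per array between 6.678 and 6.825.

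Of the probe sets, 21789 named 1 gene in the platform's annotation, 1621 several and 12147 none. The first kind alone was used. For the 999 genes with more than 1 probe set the one with the highest mean was taken, which left 19938 genes. The assembly GRCm38 served only for gene names and for the order of genes on chromosome 1, and 21698 of the probe sets with 1 gene were found in its RefSeq table. Raw intensities were not analysed here.

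A mean for each of the 8 groups was fitted to each gene with limma 3.58.1 in R 4.3.3, with its moderated test (8 residual and 5.03 prior degrees of freedom) and Benjamini-Hochberg adjustment over the 19938 genes. A gene was called at an adjusted p under 0.05. Where no gene differs, chance alone gives an unadjusted p under 0.05 to a share of 0.05 of the 19938 genes. All tests were two-sided. The contrasts were the DSS effect averaged over the 4 SIgA groups and within each, the effects of passive and of active SIgA averaged over all groups, in untreated mice and after DSS, the pairwise interactions and the three-way interaction. DSS effects are DSS minus untreated, and SIgA effects are without minus with. Changes are given as log2 differences ± standard error. The p-values measure the spread between pools of mice, not between single mice, and dam genotype was assigned by litter, so that litter effects enter the passive SIgA comparison. The number of arrays limits the precision. Tested on simulated data with the same residual spread, the fit recovered 97% of changes of 0.5 log2 for the average DSS effect, 10.4% to 28.4% of them for a DSS effect within 1 SIgA group, 88.1% to 95.5% of changes of 1 log2 for the latter, and 6% of changes of 1 log2 for the three-way term.

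The contrasts, the alternatives, the rule for named genes and 34 gene lists were fixed before the data were examined. Named genes were the 10 highest and 10 lowest changes past the threshold whose sign was the same in each matched pair of groups (for a single pair of groups, pools that did not overlap), transcripts with the symbols of unnamed, predicted, microRNA, Snor, Scarna and olfactory or vomeronasal receptor genes left aside. This goes by symbol, so that small RNAs named otherwise, such as Rnu3a, were kept. Where none passed, the 3 genes with the smallest p were taken. Of each list up to 4 members with the smallest p could be named, and Pigr throughout. Other list members and the genes named beside counts of a few genes were chosen after their values were seen. The lists covered epithelial functions (antimicrobial defence, cytokines and chemokines, interferon, MHC class I and II, pattern recognition, IgA transport, tight junctions, ion transport, xenobiotic, fatty acid and sterol metabolism, unfolded protein response, hypoxia, oxidative phosphorylation, cell cycle, wound repair), epithelial cell types (goblet, absorptive, enteroendocrine, tuft, crypt stem), other cell types that an isolate could hold (neutrophil, monocyte and macrophage, T cell, B cell, fibroblast, smooth muscle, endothelial, neuron and glia), immediate early, circadian clock and sex-linked genes, and neighbours of Pigr. Each was tested with camera at a preset correlation of 0.01, two-sided and adjusted over the 34 lists within a comparison, and as alternatives with an estimated correlation and with fry. Members were counted over all genes and adjusted over the list alone.

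The alternatives fixed in this way were limma with a trend in the prior variance, no moderation, array weights, a replicate block, arrays centred on their median, quantile normalization of the genes tested, leaving out the dimmest 30% of genes, all probe sets, a fold change of at least 1.5, an adjusted p under 0.1, a fit of only the arrays compared and leaving out each array in turn. When 1 array of a group was left out, the lone array was assumed to vary like the other groups. Leaving out both arrays of the untreated group with passive and active SIgA, leaving out these and 1 more array that stood with them on the first principal component, and an additive fit of the arrays compared were added after the data were seen. Random splits of the arrays, 100 or all 35, gave the counts of other groupings, in which the remaining factors, DSS included, need not be balanced. Tables and figures were made with Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9.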

Results

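Gene expression was measured in colonic epithelial cells of C57BL/6 mice on 16 whole-transcript arrays, each carrying RNA pooled from 3 mice. The mice differed in 3 ways. Passive SIgA is secretory IgA received in early life in the mother's milk, present when the dam was Pigr+/- and absent when the dam was Pigr-/-. Active SIgA is secretory IgA transported by the offspring's own Pigr, the receptor that carries polymeric IgA across the epithelium, present in Pigr+/- offspring and absent in Pigr-/- offspring. The mice, 70 days old, were then left untreated or drank 2% dextran sulfate sodium (DSS), an agent that injures the colonic epithelium, for 8 days. These factors gave 8 groups of 2 arrays, thus 6 mice per group: passive and active, passive only, active only, or neither, each untreated and after DSS. The values were on the log2 scale and ran from 1.857 to 14.938, and 19938 genes were tested. Medians per array ran between 6.678 and 6.825. The number of arrays limits the precision: an average DSS effect had a median standard error of 0.075 log2, and a DSS effect within 1 SIgA group one of 0.15.

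Pigr, the targeted gene, was lower in Pigr-/- than in Pigr+/- offspring in every matched pair of groups (n = 2 arrays per group, mean ± SD, log2). In untreated mice Pigr stood at 12.42 ± 0.04 with passive and active SIgA, 12.26 ± 0.11 with active SIgA only, 11.52 ± 0.13 with passive SIgA only and 11.69 ± 0.01 with neither. After DSS the same groups stood at 12.38 ± 0.00, 12.45 ± 0.02, 11.37 ± 0.04 and 11.53 ± 0.07. The difference over all arrays was -0.85 ± 0.05 log2 (SE, adjusted p = 9.77e-06), a factor of 1.8 between 8 arrays and 8 arrays, and it stayed between -0.873 and -0.826 when any 1 array was left out. Every array was thus on the side of its label for offspring genotype. Signal remained in Pigr-/- offspring, whose single arrays stood at 11.34 to 11.70, far above the array medians, and the array does not show which transcript gave it. No gene offers such a check for the dam's genotype.

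Both arrays of the untreated group with passive and active SIgA stood apart from the other 14. The mean level of 1268 chemosensory receptor and keratin-associated genes, which colonic epithelium is not known to use, was 5.26 and 5.41 in these 2 arrays and 4.45 to 4.87 in all others. In that group 1553 genes lay above and 1335 below every array of the other groups, where the other 7 groups had 31 to 643 above and 61 to 411 below. Chance gives this to 0.83% of genes in each direction. The correlation over genes of these arrays with arrays of other groups reached 0.986 and 0.981, against 0.989 to 0.997 for the other 14. On the first principal component, which held 34.1% of the variance, these arrays stood at -33.5 and -35.2, and untreated replicate 1 of active SIgA only stood with them at -32.2, while the other 13 ran from -5.5 to 27.4. That array had the highest mean of the same 1268 genes among the other 14 (4.87), and the difference between its group's replicates had the widest spread (SD 0.346 log2 over genes, 0.187 to 0.317 in the other groups). Gene counts below are therefore also given without the untreated group with passive and active SIgA, an alternative chosen after the data were seen, in which only the 7 other groups enter a comparison. A second such alternative left out all 3 of these arrays.

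**Figure D1:**
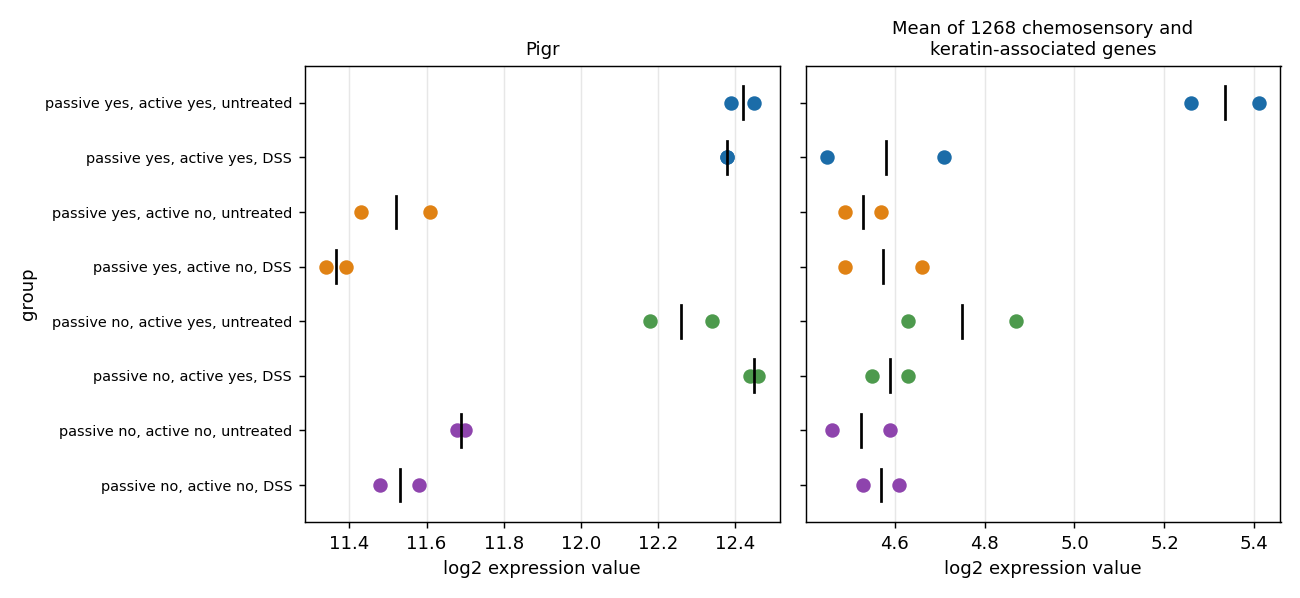
Pigr (log2) and the mean log2 level of 1268 chemosensory receptor and keratin-associated genes in each of the 16 arrays, by group. Points are arrays, each a pool of 3 mice, and bars are group means. Pigr separated the offspring genotypes, and the 2 arrays of the untreated group with passive and active SIgA lay at 5.26 and 5.41 for the second measure.

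The first comparison asked how the colonic epithelium responded to DSS, averaged over the 4 SIgA groups (8 arrays against 8). The strongest rises were in Clca4b, of the calcium-activated chloride channel regulator family, at 3.68 ± 0.15 log2 (adjusted p = 1.16e-08), a factor of 12.8. Genes of acute inflammation followed: the chemokine Ccl3 rose by 3.12 ± 0.14 and the granule proteoglycan serglycin (Srgn) by 2.99 ± 0.12. Acod1, which makes itaconate in activated myeloid cells, rose by 2.96 ± 0.18, and Il1f9, which encodes interleukin 36 gamma, by 2.74 ± 0.17. The antibacterial lectins Reg3g and Reg3b rose by 2.85 ± 0.18 and 2.60 ± 0.12. Clec4e, a receptor for microbial glycolipids, rose by 2.59 ± 0.16, Lrg1 by 2.53 ± 0.17 and the neutrophil chemoattractant Cxcl2 by 2.48 ± 0.10. Among the strongest falls were Mptx1, a mucosal pentraxin, at -1.98 ± 0.21 (adjusted p = 3.75e-05), and the sugar phosphate transporter Slc37a2 at -1.72 ± 0.07. Tppp3, which promotes tubulin polymerisation, stood at -1.66 ± 0.12, the fucosyltransferase Fut9 at -1.54 ± 0.12 and Nxpe2 at -1.51 ± 0.10. The phosphate transporter Slc34a2 (-1.44 ± 0.13), carboxypeptidase M (Cpm, -1.34 ± 0.09), the somatostatin receptor Sstr1 (-1.32 ± 0.10), transthyretin (Ttr, -1.30 ± 0.10) and Naaladl1 (-1.28 ± 0.09) fell too. All 20 of these genes moved in the same direction in each of the 4 SIgA groups, which the rule for named genes required.

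In all, 2618 genes changed with DSS, 1276 higher and 1342 lower, by limma at an adjusted p under 0.05. Without the untreated group with passive and active SIgA 1210 changed (574 higher, 636 lower), of which 1182 were among the 2618. With all 3 arrays at that end of the first component left out 1107 changed (498 higher, 609 lower), 1030 of them among the 2618. The chemosensory receptor and keratin-associated genes made up 308 of the 2618. Pigr itself did not pass, at -0.04 ± 0.06 without that group.

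**Figure D2:**
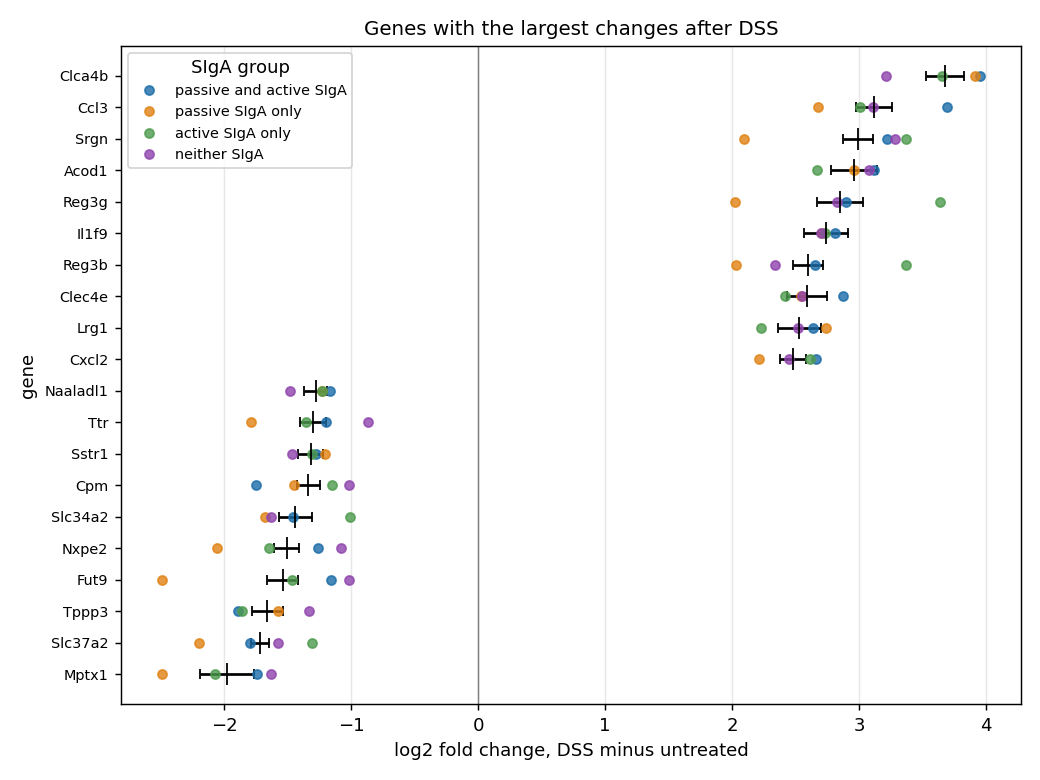
Log2 difference, DSS minus untreated, of the 10 genes with the strongest rises and the 10 with the strongest falls among genes whose sign was the same in each SIgA group. Points are the 4 SIgA groups, and bars are their mean with its standard error. Clca4b, at a mean of 3.68, and Mptx1, at -1.98, stood at the ends.

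Epithelial defence genes rose with DSS. Of 23 antimicrobial defence genes measured, 12 rose and 1 fell (15 and 2 adjusted over the list alone). The list as a whole was higher (camera adjusted p = 2.89e-12, and adjusted p = 0.00326 with an estimated correlation). The nitric oxide synthase Nos2 rose by 2.28 ± 0.08, the resistin-like goblet cell product Retnlb by 2.16 ± 0.12, the phospholipase Pla2g2a by 1.88 ± 0.08 and Duoxa2, needed by the oxidase Duox2, by 1.83 ± 0.12. Wfdc2 fell (-0.66 ± 0.07). Of 29 cytokines and chemokines, 10 rose and none fell (11 rose and 1 fell adjusted over the list alone), with adjusted p = 2.29e-09, and adjusted p = 0.0317 with an estimated correlation. Il1b rose by 2.35 ± 0.16, Il1a by 2.27 ± 0.14, the prostaglandin synthase Ptgs2 by 1.53 ± 0.16 and Ccl20, which attracts lymphocytes and dendritic cells, by 1.48 ± 0.12. Myeloid cell markers moved with both lists. Of 19 neutrophil markers, 13 rose and none fell (14 rose adjusted over the list alone; median 0.76, adjusted p = 8.88e-15, and adjusted p = 0.0376 with an estimated correlation). Among them were Trem1 at 1.60 ± 0.15, Retnlg at 1.54 ± 0.10, the histamine-forming enzyme Hdc at 1.03 ± 0.08 and S100a8 at 1.11 ± 0.09. Of 22 monocyte and macrophage markers, 11 rose and none fell (12 rose adjusted over the list alone; adjusted p = 7.70e-10, and adjusted p = 0.0427 with an estimated correlation). Among them were the oxidase subunit Cybb at 1.12 ± 0.11 and the signalling adaptors Fcer1g at 0.99 ± 0.09 and Tyrobp at 0.98 ± 0.11.

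Antigen presentation and innate signalling genes rose as well, with list tests that passed at the preset correlation of 0.01 and not with an estimated one. By fry the MHC class II (adjusted p = 6.60e-05), MHC class I (adjusted p = 0.00086) and pattern recognition lists (adjusted p = 0.00038) passed and the interferon list did not (adjusted p = 0.156). Of 9 MHC class II genes, 5 rose and none fell, also adjusted over the list alone (adjusted p = 4.61e-06, and adjusted p = 0.0725 with an estimated correlation). The invariant chain Cd74 rose by 1.79 ± 0.16, H2-Ab1 by 1.37 ± 0.11, H2-Aa by 1.35 ± 0.14, H2-Eb1 by 0.91 ± 0.07 and H2-DMa by 0.61 ± 0.08. Of 11 MHC class I and immunoproteasome genes, 7 rose, also adjusted over the list alone, with Psmb8 at 0.58 ± 0.07 and the peptide transporter Tap1 at 0.51 ± 0.12 (adjusted p = 4.70e-05, and adjusted p = 0.107 with an estimated correlation). Of 26 pattern recognition and NF-kB genes, 9 rose and 1 fell (12 and 1 adjusted over the list alone; adjusted p = 1.81e-06, and adjusted p = 0.0725 with an estimated correlation). Among them were Tnfaip2 at 1.19 ± 0.12, the lipopolysaccharide co-receptor Cd14 at 0.99 ± 0.08 and the fall in Traf1 at -0.34 ± 0.07. Of 28 interferon-stimulated genes, 6 rose and 1 fell (11 and 2 adjusted over the list alone; adjusted p = 0.000276, and adjusted p = 0.538 with an estimated correlation). The tryptophan-degrading enzyme Ido1 rose by 1.79 ± 0.20, the chemokine Cxcl9 by 1.06 ± 0.11 and the nucleic acid sensor Zbp1 by 1.03 ± 0.13, while Irf7 fell (-0.53 ± 0.11). The myeloid markers above rose in the same arrays as these genes.

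Genes of the differentiated colonic surface and of the crypt base fell with DSS. Of 24 ion transport genes, 14 fell and 1 rose (16 and 1 adjusted over the list alone; median -0.21, adjusted p = 1.05e-09, and adjusted p = 0.0427 with an estimated correlation). They included the chloride channel Ano1 at -1.20 ± 0.06, the anion channel Best2 at -1.23 ± 0.09, the water channel Aqp8 at -0.96 ± 0.10 and the sodium channel subunit Scnn1a at -0.76 ± 0.08. Of 28 absorptive colonocyte markers, which share Aqp8 and Scnn1a with that list, 13 fell and 3 rose (15 and 4 adjusted over the list alone; adjusted p = 0.000115, and adjusted p = 0.241 with an estimated correlation). The rises were B3galt5 at 0.64 ± 0.06, Aqp4 at 0.53 ± 0.06 and Clca4a at 0.37 ± 0.08. Of 19 crypt stem and progenitor markers, 9 fell and 1 rose, also adjusted over the list alone (adjusted p = 4.23e-05, and adjusted p = 0.0725 with an estimated correlation). Among them were the Wnt co-receptor Lgr5 at -0.94 ± 0.09, Ephb3 at -0.67 ± 0.07, the stem cell transcription factor Ascl2 at -0.61 ± 0.09, and Prom1 with a rise of 0.48 ± 0.07. Of 37 xenobiotic metabolism genes, 16 fell and none rose (22 fell adjusted over the list alone; adjusted p = 1.05e-09, and adjusted p = 0.102 with an estimated correlation). The cytochromes Cyp4b1 (-1.03 ± 0.10) and Cyp2s1 (-0.60 ± 0.06) and the sulfotransferase Sult1a1 (-0.61 ± 0.08) were among them. Of 29 fatty acid oxidation genes, 6 fell and 1 rose (8 and 1 adjusted over the list alone; adjusted p = 0.0175, and adjusted p = 0.226 with an estimated correlation). They held the mitochondrial coactivator Ppargc1a at -0.59 ± 0.07, the fatty acid binding protein Fabp2 at -0.55 ± 0.08 and a rise in Acadl of 0.59 ± 0.07. Of 21 immediate early genes, 6 fell and 1 rose (13 and 2 adjusted over the list alone), with Nr4a1 at -0.60 ± 0.08, Fosb at -0.59 ± 0.09 and Ier3 at 0.55 ± 0.07 (adjusted p = 0.000156, and adjusted p = 0.242 with an estimated correlation).

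Genes of growth, repair and cell stress rose. Of 21 hypoxia and glycolysis genes, 9 rose and 1 fell (11 and 1 adjusted over the list alone; adjusted p = 1.03e-06, and adjusted p = 0.0427 with an estimated correlation). The glycolytic regulator Pfkfb3 rose by 0.99 ± 0.14, the oxygen sensor Egln3 by 0.65 ± 0.08, Ero1a by 0.61 ± 0.06 and the lactate transporter Slc16a3 by 0.53 ± 0.06, while Vegfa fell (-0.24 ± 0.06). Of 26 unfolded protein response genes, 12 rose and 1 fell (14 and 1 adjusted over the list alone), with Creld2 at 0.60 ± 0.09, Sdf2l1 at 0.60 ± 0.06 and Ern2, a goblet cell stress sensor, at -0.42 ± 0.06 (adjusted p = 1.03e-06, and adjusted p = 0.241 with an estimated correlation). Of 29 cell cycle genes, 6 rose and none fell (15 rose adjusted over the list alone), with the ribonucleotide reductase subunit Rrm2 at 0.58 ± 0.08 and the cyclin Ccna2 at 0.50 ± 0.12 (adjusted p = 1.88e-09, and adjusted p = 0.267 with an estimated correlation). Of 23 wound repair genes, 7 rose and none fell (7 and 2 adjusted over the list alone), with the plasminogen activator Plat at 0.81 ± 0.10 and the collagen receptor subunit Itga2 at 0.59 ± 0.07 (adjusted p = 0.00764, and adjusted p = 0.241 with an estimated correlation). Of 22 fibroblast and matrix markers, 5 rose and none fell (6 rose adjusted over the list alone), with vimentin (Vim) at 0.81 ± 0.10, decorin (Dcn) at 0.78 ± 0.13 and Fbln1 at 0.58 ± 0.06 (adjusted p = 0.000953, and adjusted p = 0.483 with an estimated correlation).

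The other lists did not pass as a whole. Goblet cell markers went both ways (2 of 19 rose and 4 fell; 5 and 5 adjusted over the list alone), with the trefoil peptide Tff3 at 0.38 ± 0.07 and the secretory lineage factor Atoh1 at -0.39 ± 0.08. Of 24 tight junction and adhesion genes, 2 rose and 4 fell, with the claudin Cldn4 at -0.51 ± 0.10 and the desmosomal Dsc2 at 0.41 ± 0.06. Of 16 circadian clock genes, 4 fell (Cry2 at -0.49 ± 0.10), of 24 sterol and lipid synthesis genes 2 rose and 2 fell (Scd1 at -0.57 ± 0.11), and of 12 IgA transport and class switching genes 2 rose and 1 fell (Tnfsf13b at 0.33 ± 0.08). Of 18 tuft cell markers, 1 rose and 1 fell, and of 19 enteroendocrine markers Pcsk1 alone passed, at -0.35 ± 0.09. None of 24 T cell, 16 endothelial, 25 oxidative phosphorylation or 6 sex-linked genes passed. Of 22 B cell and plasma cell markers, Igha, the IgA heavy chain, fell (-0.61 ± 0.14) with Sdc1 (-0.33 ± 0.05). Igha stood at -0.24 ± 0.17 (adjusted p = 0.59) without the untreated group with passive and active SIgA, while Pcsk1 (-0.31 ± 0.09), Ccna2 (0.52 ± 0.14, adjusted p = 0.0507), Cldn4 (-0.45 ± 0.12, adjusted p = 0.0521) and Alox5ap (0.41 ± 0.13) no longer passed there with differences of like size. Smooth muscle markers (2 of 16 rose), neuron and glia markers (1 of 14 rose) and the 30 Pigr neighbours on chromosome 1 (2 fell, 1 of them adjusted over the list alone, Ctse at -0.50 ± 0.10) complete the 34 lists. By camera 19 lists passed with the preset correlation and 6 with an estimated one, and by fry 17 did, all of the 19 but the interferon and fibroblast lists. Without the untreated group with passive and active SIgA 20 and 4 did, since the monocyte and macrophage list and the hypoxia and glycolysis list each went to adjusted p = 0.0569 with an estimated correlation.

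**Figure D3:**
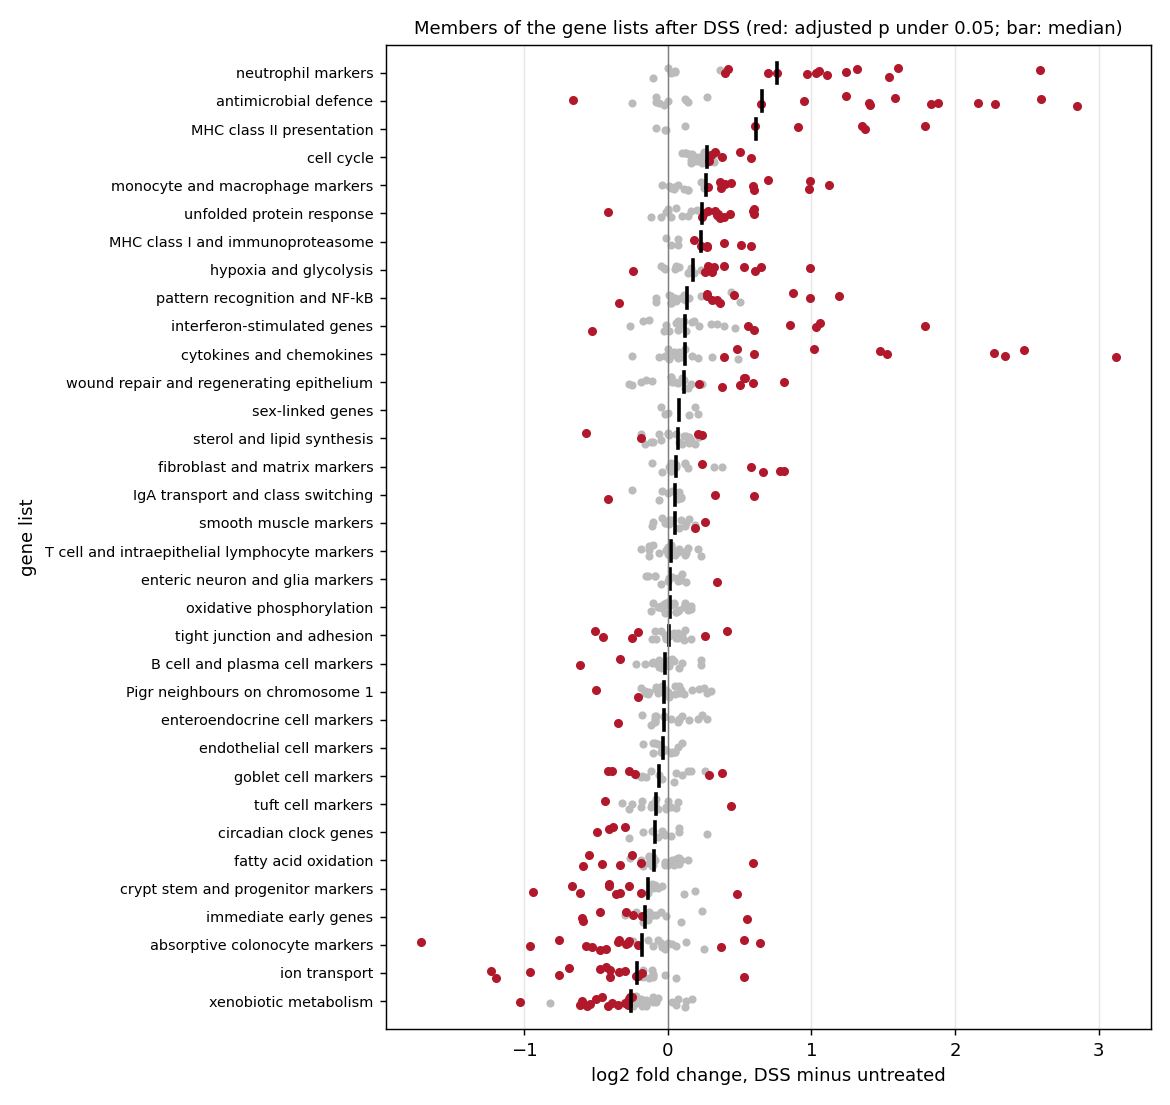
Log2 difference, DSS minus untreated, of the members of gene lists, averaged over the 4 SIgA groups. Each point is a gene, red where its adjusted p was under 0.05, and the black bar is the list's median, 0.76 for neutrophil markers and -0.21 for ion transport.

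Clca4b, Ccl3, Srgn, Acod1 and Il1f9 were among the 10 strongest rises, and Slc37a2 and Tppp3 among the 10 strongest falls, within each single SIgA group (2 arrays against 2 each, with the spread taken from all 16 arrays). Clca4b rose by 3.95 ± 0.30 with passive and active SIgA, 3.91 ± 0.30 with passive SIgA only, 3.65 ± 0.30 with active SIgA only and 3.22 ± 0.30 with neither. With passive and active SIgA, Ccl3 (3.69 ± 0.27), Il1a (3.04 ± 0.28) and Ido1 (2.93 ± 0.41) rose, while Zfp600 (-2.98 ± 0.13), Zfp980 (-1.94 ± 0.27), Ssxb10 (-1.96 ± 0.55) and Srsy (-3.06 ± 0.79) were among the strongest falls. The defensin Defb4 (-1.84 ± 0.14), Mup5 (-1.75 ± 0.16), Slc37a2 (-1.80 ± 0.15), Tppp3 (-1.89 ± 0.24) and Cpm (-1.75 ± 0.19) fell there too. With passive SIgA only, Acod1 (2.96 ± 0.36), Lrg1 (2.74 ± 0.34), Wfdc18 (2.34 ± 0.21) and Lilr4b (2.06 ± 0.32) rose. There Fut9 (-2.49 ± 0.24), Slc37a2 (-2.20 ± 0.15), Nxpe2 (-2.06 ± 0.20), Itih2 (-1.62 ± 0.20), the muscle-type enolase Eno3 (-1.60 ± 0.14) and Hmcn1 (-1.60 ± 0.19) fell. With active SIgA only, Reg3g (3.64 ± 0.36), Reg3b (3.37 ± 0.23), Srgn (3.37 ± 0.24) and Retnlb (2.66 ± 0.24) rose and Tppp3 (-1.85 ± 0.24), Best2 (-1.40 ± 0.18) and Cyp4b1 (-1.32 ± 0.19) fell. With neither, Srgn (3.28 ± 0.24), Acod1 (3.08 ± 0.36) and Il1a (2.52 ± 0.28) rose and Cyp4b1 (-1.74 ± 0.19), the peptide transporter Slc15a1 (-1.27 ± 0.17), Fxyd4 (-1.15 ± 0.16) and Aqp8 (-1.14 ± 0.20) fell.

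Antimicrobial defence genes were higher as a list in each of these groups, also with an estimated correlation: 12 of 23 rose with passive and active SIgA (13 adjusted over the list alone; estimated-correlation adjusted p = 0.00902), 10 with passive SIgA only (12; adjusted p = 0.0106), 9 with active SIgA only (14; adjusted p = 0.00101) and 10 with neither (12; adjusted p = 0.00212). Neutrophil markers were also higher on that test with passive SIgA only (10 of 19 rose) and with neither (8 rose). With neither, ion transport, absorptive colonocyte and crypt stem lists were lower on that test, with 6, 6 and 3 members falling. When the untreated group with passive and active SIgA did not enter the estimate of the spread, the absorptive and crypt stem lists went to adjusted p = 0.0545 and 0.0537 with an estimated correlation. The lists passing on that test then went from 7 to 5 with neither, from 3 to 1 with active SIgA only and stayed at 2 with passive SIgA only. Pigr did not pass in any of the 4 groups (-0.04 ± 0.10, -0.15 ± 0.10, 0.18 ± 0.10 and -0.16 ± 0.10). The counts were 2011 genes with passive and active SIgA (709 higher, 1302 lower), 394 with passive SIgA only (178 and 216), 199 with active SIgA only (124 and 75) and 223 with neither (98 and 125). The balance of directions in the first depended on the processing, with 317 higher and 2056 lower when arrays were centred on their median, and 523 higher and 227 lower without the dimmest 30% of genes. It cannot be computed without its untreated arrays, and 734 of its genes were chemosensory receptor or keratin-associated genes, where the other 3 groups had 2, 0 and 0. For the other 3 groups the counts became 310, 144 and 174 when that group did not enter the estimate of the spread, and 370, 67 and 219 with all 3 arrays left out, 1 array of active SIgA only among them. The counts with 1 array left out ran from 814 (without DSS replicate 2 of the group with passive and active SIgA) to 2486, from 107 (without untreated replicate 2 of passive SIgA only) to 486, from 64 (without DSS replicate 1 of active SIgA only) to 672 (without its untreated replicate 2), and from 54 (without untreated replicate 2 of neither) to 274.

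The next comparison asked what early passive SIgA left behind in the colonic epithelium of adult mice, as the difference without minus with passive SIgA (8 arrays against 8). Without it, Atp12a, the colonic proton and potassium pump, was higher by 0.87 ± 0.13 (adjusted p = 0.00985), the interferon regulatory factor Irf1 by 0.59 ± 0.09 and the clock repressor Nr1d2 by 0.59 ± 0.09. Small non-coding RNAs were also higher: Rnu5g by 0.60 ± 0.11, Rnu12 by 0.54 ± 0.08, Rprl2 by 0.51 ± 0.05 and Rprl1 by 0.47 ± 0.07, with the small nucleolar RNA host gene Snhg17 at 0.58 ± 0.09, Syt5 at 0.50 ± 0.08 and Gpr17 at 0.44 ± 0.08. The epithelial kinase Ptk6 was lower (-0.63 ± 0.11, adjusted p = 0.0206), as were Uprt (-0.61 ± 0.13), the annexin Anxa5 (-0.60 ± 0.13), the matricellular Ccn3 (-0.53 ± 0.08), Wfdc18 (-0.51 ± 0.11), the mucin glycosylation enzyme B3gnt6 (-0.49 ± 0.09) and Alg3 (-0.47 ± 0.08). The replication and repair genes Pclaf (-0.53 ± 0.08), Asf1b (-0.48 ± 0.08) and Rad18 (-0.46 ± 0.08) were lower too. The average for Ptk6 came mostly from the DSS groups, with means of 9.10 and 9.15 with passive SIgA and 8.34 and 7.60 without. Its untreated means were 7.30 and 7.51 with and 7.12 and 7.50 without. Among lists, the enteroendocrine markers Gcg (-0.43) and Chga (-0.36) were lower, 7 adjusted over the list alone, and 1 of 29 cell cycle genes was lower, 12 adjusted over the list alone (adjusted p = 0.605 with an estimated correlation). Of 16 circadian clock genes 1 was higher, 9 higher and 3 lower adjusted over the list alone (adjusted p = 0.605 with an estimated correlation), and levels of the clock gene Dbp ranged from 7.29 to 9.80 over the arrays. Of 34 lists 8 passed by camera and none with an estimated correlation, the lowest being adjusted p = 0.353 with an estimated correlation, while by fry the enteroendocrine list passed (adjusted p = 0.0348). Pigr did not pass (0.06 ± 0.05).

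In all, 192 genes differed (65 higher, 127 lower). When the untreated group with passive and active SIgA was left out, 3 did by limma, and these, named after their values were seen, were the small RNAs Snora33 (1.01 ± 0.12, adjusted p = 0.0153), Snord118 (0.96 ± 0.11, adjusted p = 0.0153) and Rprl2 (0.52 ± 0.06, adjusted p = 0.0167). Several genes that no longer passed had differences of like size there: Atp12a stood at 0.90 ± 0.15 (adjusted p = 0.0978), Ptk6 at -0.78 ± 0.12 (adjusted p = 0.0639), Ccn3 at -0.53 ± 0.10, Wfdc18 at -0.61 ± 0.13, Rnu5g at 0.58 ± 0.13 and Snhg17 at 0.56 ± 0.11. Irf1 (0.45 ± 0.10), Nr1d2 (0.44 ± 0.11), Syt5 (0.35 ± 0.10) and Anxa5 (-0.44 ± 0.15) stood nearer to 0. Lists passing by camera then numbered 13, none with an estimated correlation. With all 3 arrays left out 9 genes passed, all among the 192. With 1 array left out, 52 (without DSS replicate 2 of active SIgA only) to 267 genes were called.

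In untreated mice without passive SIgA (4 arrays against 4), the differences furthest above 0 were those of Ciart, a clock repressor, at 1.44 ± 0.33 (adjusted p = 0.0398), the glutathione-degrading Chac1 at 1.20 ± 0.25, Nr1d2 at 0.86 ± 0.13 and Irf1 at 0.86 ± 0.12. Next came Homer1 (0.80 ± 0.12), Syt5 (0.80 ± 0.11), the tyrosine aminotransferase Tat (0.78 ± 0.14), Atp12a (0.78 ± 0.18), the sodium and proton exchanger Slc9a3 (0.67 ± 0.16) and the integrin subunit Itgb6 (0.65 ± 0.13). Zfp600 (-1.70 ± 0.09), Zfp980 (-1.27 ± 0.19), the nuclear body protein Sp140 (-1.11 ± 0.22), Scgb2b2 (-0.96 ± 0.09), Anxa5 (-0.94 ± 0.18), Uprt (-0.90 ± 0.18), Mup5 (-0.85 ± 0.11), Srgn (-0.85 ± 0.17), Retnlb (-0.82 ± 0.17) and the claudin Cldn8 (-0.82 ± 0.19) were lower. With the untreated group with passive and active SIgA left out, the contrast rests on passive SIgA only against neither. There Ciart stood at 1.78 ± 0.48, Retnlb at -1.38 ± 0.24 (adjusted p = 0.26), Zfp600 at -0.35 and Scgb2b2 at -0.16, none past the threshold. The lists called were interferon-stimulated genes and smooth muscle markers higher and cell cycle genes lower (5 of 29 adjusted over the list alone, none over all genes), each at adjusted p = 0.929 with an estimated correlation. The interferon call held Irf1 and Irf9 (0.55 ± 0.11). Pigr stood at 0.01 ± 0.07. In all 514 genes differed (155 higher, 359 lower), 216 of them chemosensory receptor or keratin-associated genes. Without that group limma called 0 (1379 at an unadjusted p under 0.05), with a median standard error of 0.151 in place of 0.106, and 11 lists passed by camera, none with an estimated correlation. It also called 0 with all 3 arrays left out (1674 at an unadjusted p under 0.05). Counts with 1 array left out ran from 157 (without untreated replicate 1 of passive SIgA only) to 714.

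After DSS, limma called 0 genes between mice without and with passive SIgA (4 arrays against 4; 788 at an unadjusted p under 0.05, fewer than the share of 0.05 of the 19938 genes that chance alone would give). This 0 depends on the fit: 16 genes passed with replicates of the same number taken as a block, 25 with limma-trend and 15 without the dimmest 30% of genes. The genes named by the rule were Ptk6 (-1.16 ± 0.15), the small nucleolar RNA gene Rnu3a (0.93 ± 0.14) and the pantetheinase Vnn1 (-0.60 ± 0.09), each at adjusted p = 0.0645. Snord118, which the rule leaves aside by its symbol, also stood at adjusted p = 0.0645. The untreated group with passive and active SIgA enters here only through the estimate of the spread, and without it Ptk6 (adjusted p = 0.0403) and Snord118 (1.19 ± 0.13, adjusted p = 0.0177) passed, and 4 genes did with all 3 arrays left out. Enteroendocrine markers were lower as a list (median -0.12, adjusted p = 4.39e-09, and adjusted p = 0.0305 with an estimated correlation, or 0.0588 without that group; by fry adjusted p = 0.0201), with 0 of 19 members past the threshold over all genes and 8 lower adjusted over the list alone. Chromogranins Chga (-0.49 ± 0.10) and Chgb (-0.41 ± 0.10), the serotonin-forming enzyme Tph1 (-0.53 ± 0.12) and proglucagon (Gcg, -0.50 ± 0.12) were those with the smallest p. The other lists called, 10 in all with this one, had an adjusted p of at least 0.457 with an estimated correlation. Cell cycle genes were among those lower and endothelial markers, ion transport and clock genes among those higher. The neutrophil list was called lower too, but its direction by camera turned without the dimmest 30% of genes. The 6 sex-linked genes went apart without passing, with Kdm5d at -0.62 ± 0.27, Uty at -0.61 ± 0.34 and Xist at 0.40 ± 0.21 (list adjusted p = 0.528, and adjusted p = 0.804 with an estimated correlation), and the labels do not give the mixture of sexes in a pool. Pigr stood at 0.12 ± 0.07.

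The comparison by offspring genotype asked what the loss of active SIgA transport changed, as Pigr-/- minus Pigr+/- (8 arrays against 8). Beside Pigr, the endosomal protease cathepsin E (Ctse), a neighbour of Pigr on chromosome 1, was lower (-0.66 ± 0.10, adjusted p = 0.0109) and Pm20d1, an enzyme of N-acyl amino acids encoded on the same stretch, was higher (0.54 ± 0.08, adjusted p = 0.0109). The spliceosomal Snrpe (0.58 ± 0.11), the goblet cell marker Bcas1 (0.46 ± 0.10), Nol10 (0.44 ± 0.07), Lgr5 (0.41 ± 0.09), Spats2 (0.37 ± 0.06), Fam111a (0.34 ± 0.06), Far2 (0.33 ± 0.06), N4bp2 (0.29 ± 0.06) and the transcription factor Nfib (0.29 ± 0.06) were also higher. The small heat shock protein Hspb1 (-0.61 ± 0.13), Krtap24-1 (-0.51 ± 0.08), Cyp4a12b (-0.51 ± 0.09), Mup5 (-0.48 ± 0.08), Cst9 (-0.48 ± 0.09), the peptide hormone Apela (-0.48 ± 0.08), Tdpoz3 (-0.47 ± 0.07) and Pramel7 (-0.44 ± 0.10) were lower. Of 19 goblet cell markers 2 were higher, 6 adjusted over the list alone (adjusted p = 6.84e-06, and adjusted p = 0.180 with an estimated correlation). Crypt stem markers (1 of 19 higher, 6 adjusted over the list alone), cell cycle, xenobiotic metabolism and ion transport genes were also higher as lists and monocyte and macrophage markers lower, each at adjusted p = 0.336 or more with an estimated correlation. By fry the goblet cell (adjusted p = 0.00639) and crypt stem lists (adjusted p = 0.0328) were higher and the IgA transport list lower (adjusted p = 0.0328). The IgA transport list holds Pigr, the targeted gene, and was not tested without it, so its call shows no wider change. In all 274 genes differed (18 higher, 256 lower), of which 197 were chemosensory receptor or keratin-associated genes. Pigr alone did without the untreated group with passive and active SIgA (-0.83 ± 0.06, adjusted p = 0.000316), and 1 gene did with all 3 arrays left out. Without that group Ctse (-0.65 ± 0.12), Pm20d1 (0.61 ± 0.09, adjusted p = 0.325), Snrpe (0.62 ± 0.13) and Hspb1 (-0.66 ± 0.14) kept differences of like size and did not pass. Mup5 (-0.09 ± 0.08), Krtap24-1 (-0.18 ± 0.09), Apela (-0.22 ± 0.10), Tdpoz3 (-0.21 ± 0.08) and N4bp2 (0.15 ± 0.08) stood nearer to 0. Lists passing by camera rose from 6 to 16, none with an estimated correlation. With 1 array left out the count ran from 58 (without DSS replicate 1 of neither) to 1043 (without untreated replicate 2 of active SIgA only).

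In untreated mice Pigr was lower in Pigr-/- offspring (-0.74 ± 0.07, adjusted p = 0.000286; 4 arrays against 4). Retnlb was higher by 1.08 ± 0.17 (adjusted p = 0.00258), and the class II genes Cd74 by 1.05 ± 0.23 and H2-Ab1 by 0.79 ± 0.15. Also higher were Rny1 (0.88 ± 0.19), Cyp2c67 (0.73 ± 0.20), Snrpe (0.71 ± 0.15), Bcas1 (0.70 ± 0.15), Apol10a (0.70 ± 0.19), the deubiquitinase Usp1 (0.69 ± 0.19) and Nkap (0.69 ± 0.16). Igha was lower (-1.07 ± 0.20, adjusted p = 0.0085). So were Prl3d3 (-1.14 ± 0.19), Skint11 (-0.97 ± 0.17), Ugt3a1 (-0.96 ± 0.16), Cyp4a12a (-0.93 ± 0.23), Npy6r (-0.91 ± 0.14), Cldn34-ps (-0.90 ± 0.20), Mup5 (-0.90 ± 0.11), the taste receptor Tas2r118 (-0.87 ± 0.17) and Krtap24-1 (-0.86 ± 0.11). Leaving that untreated group with passive and active SIgA out leaves active SIgA only against neither. The group with passive SIgA only, where Cd74, H2-Ab1 and Retnlb stood highest, thus drops out too. There Pigr stood at -0.57 ± 0.11 (adjusted p = 0.45), Retnlb at 0.51 ± 0.24, Cd74 at 0.02 ± 0.34, Igha at -0.55 ± 0.30 and Snrpe at 0.94 ± 0.22, none past the threshold. The lists called were antimicrobial defence (3 of 23 higher; adjusted p = 0.280 with an estimated correlation), goblet cell markers (2 of 19 higher; adjusted p = 0.280 with an estimated correlation), and crypt stem markers (3 of 19 higher; adjusted p = 0.558 with an estimated correlation). MHC class II (3 of 9), ion transport (2 of 24), cell cycle and xenobiotic metabolism genes followed, each higher at adjusted p = 0.703 with an estimated correlation. B cell and plasma cell markers were lower (3 of 22: Igha, Cr2 and Ms4a1), again at adjusted p = 0.703 with an estimated correlation. By fry the antimicrobial (adjusted p = 0.0202) and goblet cell lists (adjusted p = 0.00973) passed. Adjusted over the list alone, the members passing were 4 higher and 2 lower, 4 higher, 3 higher, 3 higher, 2 higher, 0, 0 and 3 lower, in that order. In all 1494 genes differed (313 higher, 1181 lower), of which 713 were chemosensory receptor or keratin-associated genes, and without that group limma called 0 (2176 at an unadjusted p under 0.05) and 19 lists passed by camera, none with an estimated correlation. With all 3 arrays left out limma also called 0 (793 at an unadjusted p under 0.05). Counts with 1 array left out ran from 476 (without untreated replicate 2 of neither) to 4718 (without untreated replicate 2 of active SIgA only).

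After DSS, Pigr was the 1 gene that differed by offspring genotype (-0.96 ± 0.07, adjusted p = 0.000147; 4 arrays against 4; 330 genes at an unadjusted p under 0.05), and it was also the 1 gene without the untreated group with passive and active SIgA (-0.96 ± 0.08, adjusted p = 0.000609). The 330 are fewer than the share of 0.05 of the 19938 genes that chance alone would give. The inflammatory genes Ccl3 (-0.63 ± 0.19), Il6 (-0.52 ± 0.14) and Psmb8 (-0.34 ± 0.10) did not pass. Of 34 lists 16 passed by camera and none with an estimated correlation. Cytokines and chemokines (adjusted p = 6.81e-07) and MHC class I genes (adjusted p = 5.08e-07) were lower and goblet cell markers higher (adjusted p = 0.000136), each at adjusted p = 0.137 with an estimated correlation, with none of their members past the threshold, also adjusted over the list alone. Monocyte and macrophage markers were lower in the same arrays (adjusted p = 0.0006, and adjusted p = 0.296 with an estimated correlation), as were the 6 sex-linked genes (adjusted p = 0.00783, and adjusted p = 0.145 with an estimated correlation), where Uty stood at -0.34 ± 0.34 and Eif2s3y at -0.29 ± 0.37.

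The last comparisons asked whether the effects of passive SIgA, active SIgA and DSS depended on one another. Zfp600, a zinc finger gene, led each: the DSS effect was higher by 1.82 ± 0.13 without passive than with passive SIgA (adjusted p = 5.62e-05) and by 1.53 ± 0.13 without than with active SIgA. Its passive effect differed with offspring genotype (adjusted p = 0.000589), and its three-way term was -2.38 ± 0.26. Its level was 5.61 ± 0.05 (SD) in the untreated group with passive and active SIgA and 2.57 to 2.95 in every other group. Mup5 (1.01 ± 0.16), Scgb2b2 (0.87 ± 0.13) and Nyx (0.70 ± 0.12) also differed in their DSS effect by passive SIgA. By active SIgA, Prl3d3 (1.34 ± 0.26), Cyp2c39 (1.30 ± 0.21), Skint11 (1.15 ± 0.24), Defb4 (1.08 ± 0.14), the taste receptor Tas2r114 (0.88 ± 0.17), Mup5 (0.82 ± 0.16), Nyx (0.80 ± 0.12), Zfp979 (0.77 ± 0.16) and Mucl2 (0.75 ± 0.12) differed upward and Klb, a co-receptor of fibroblast growth factors, downward (-0.51 ± 0.10). Scgb2b2 (0.98 ± 0.13) carried the passive by active term and Mucl2 (-1.61 ± 0.23) the three-way term. Leaving out that untreated group narrows these terms. The DSS effect by passive SIgA is then compared in Pigr-/- offspring alone and that by active SIgA in mice without passive SIgA alone. The passive by active term then rests on the DSS groups alone. There the DSS effect of Zfp600 differed by passive and by active SIgA by 0.63 ± 0.19 and 0.34 ± 0.19, that of Mup5 by 0.22 ± 0.20 and 0.03 ± 0.20, and that of Nyx by 0.10 ± 0.17 and 0.19 ± 0.17. By passive SIgA Scgb2b2 then stood at 0.24 ± 0.18, and by active SIgA Defb4 stood at 0.28 ± 0.21, Mucl2 at -0.06 ± 0.17, Prl3d3 at 0.82 ± 0.19, Cyp2c39 at 0.84 ± 0.31 and Skint11 at 0.78 ± 0.33, none past the threshold. Pigr did not pass in any of the 4 (0.11 ± 0.10, -0.23 ± 0.10, 0.21 ± 0.10 and -0.23 ± 0.21). Lists passed by camera for 2, 9, 0 and 10 of the 34, and none by fry or with an estimated correlation, the lowest being adjusted p = 0.29 with an estimated correlation. Without the untreated group with passive and active SIgA 10, 19 and 8 passed for the first 3 terms, none with an estimated correlation.

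The counts were 23 genes for passive SIgA by DSS (all higher), 168 for active SIgA by DSS (167 higher, 1 lower), 15 for passive by active SIgA and 12 for the three-way term. Of these, 17, 143, 12 and 7 were chemosensory receptor or keratin-associated genes. Without the untreated group with passive and active SIgA the first 3 terms are the narrower contrasts named above, with a median standard error of 0.214 in place of 0.15. For each of them limma then called 0 genes (777, 673 and 380 at an unadjusted p under 0.05, each under the share of 0.05 that chance alone would give), and the three-way term could not be estimated. It again called 0 for each with all 3 arrays left out (965, 420 and 467 at an unadjusted p under 0.05). With 1 array left out, limma called 1 to 84, 34 to 527, 4 to 60 and 3 to 65 genes.

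**Figure D4:**
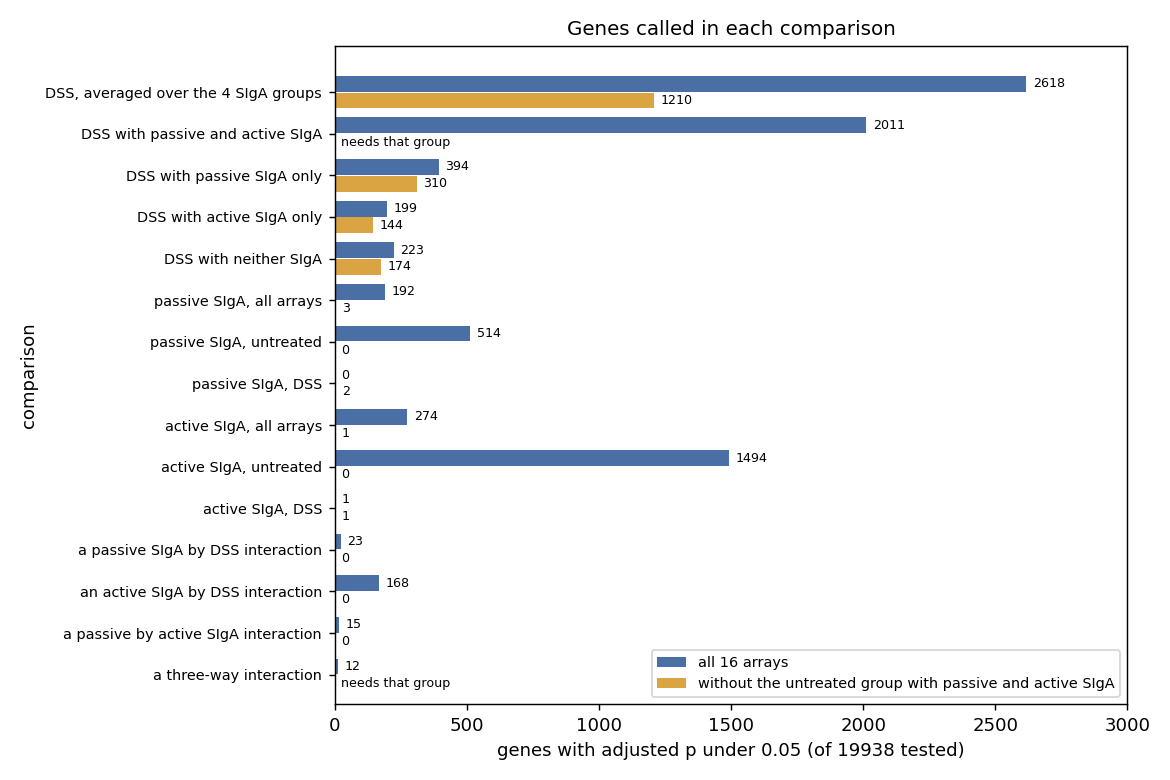
Number of genes past an adjusted p of 0.05 in each comparison, with all 16 arrays and without the untreated group with passive and active SIgA. The DSS count went from 2618 to 1210 and the untreated active SIgA count from 1494 to 0. Without that group the latter compares 2 arrays against 2 in place of 4 against 4. Its median standard error was then 0.151 in place of 0.106, and Pigr itself did not pass.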

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

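The splits of the arrays, the test of 2 arrays differing in preparation and the comparison of other cell type lists were chosen only after the result was seen, and so was leaving out the untreated group with passive and active SIgA. A first set of splits used an additive fit of the split beside the other factors and their interaction, whose real counts are not those reported. It was replaced by splits with a mean for each group after its outcome was known, and both are given.

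Interaction tests gave a difference between groups in the DSS effect by passive SIgA for 23 genes and by active SIgA for 168 genes. They gave a difference in the passive effect by active SIgA for 15 genes, and 12 genes had a three-way interaction. Among data the comparisons did not use, 1328 of 15619 remaining probe sets changed with DSS, 296 higher and 1032 lower. They include further probe sets of genes that were tested. The untreated group with passive and active SIgA entered this count, which was not made without it. Among the genes tested, 307 of the 308 chemosensory receptor and keratin-associated genes called with DSS were lower.

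For DSS, 1 of 100 splits of the 16 arrays (of 6435 possible), the real one, gave as many genes as the real 2618, and the highest other gave 2202. The real split keeps the pools of a group together, while other splits mostly mix groups. That widens their residual spread and favours the real split, so its rank does not by itself exclude chance. Nor do these splits exclude chance for the SIgA comparisons that called more than 1 gene. Passive SIgA had 5 of 100 splits with at least the real 192 genes (highest other 1368) and 5 of 35 with at least 514 in untreated mice (highest other 2346). After DSS it called 0 genes, which 35 of 35 splits meet by construction (highest other 1), so that this count tests nothing. Active SIgA had 6 of 100 with at least 274 (highest other 798) and 2 of 35 with at least 1494 in untreated mice (highest other 2346). After DSS 3 of 35 had at least 1 gene (highest other 1), a count that any split with a single call ties. Only the real split called Pigr, whose difference between the sides, 0.96 log2 in size, was reached by 1 of the 35, the real one (highest other 0.57). Every other split mixes the offspring genotypes, and Pigr in every array was on the side of its label. For this targeted gene the rank was thus fixed in advance and does not test chance. The interactions had 27 of 100 with at least 23 (highest other 1632), 7 of 100 with at least 168 (1542), 41 of 100 with at least 15 (1639) and 36 of 100 with at least 12 (707). Splits that called several times the real count point to a structure of the samples: wherever the 2 untreated arrays with passive and active SIgA took part, the split with the highest count kept both on 1 side. Over all arrays those splits were not balanced for DSS either. On 1 side, 7 of 8 arrays were untreated for active SIgA. It was 6 of 8 for passive SIgA, passive SIgA by DSS and passive by active SIgA. For active SIgA by DSS and the three-way term it was 5 of 8, nearer to balance. The less balanced splits carry the DSS effect as well, which these counts cannot part from that structure.

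With the additive fit, 1 of 100 splits gave as many as 2049 genes for DSS (highest other 1186), 3 of 100 as many as 52 for passive SIgA (127), 1 of 35 as many as 3 for passive SIgA after DSS (1), 3 of 100 as many as 1 for active SIgA (2) and 2 of 35 as many as 1 for active SIgA after DSS (2). The shares for passive SIgA over all arrays and after DSS and for active SIgA over all arrays were thus under 0.05 with that fit and not with the other. In untreated mice and for each interaction the additive fit called 0 genes, so that every split gave as many and nothing was tested.

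In the untreated group with passive and active SIgA, 63.8% of 1268 chemosensory receptor and keratin-associated genes lay above every other array in both of its arrays. A shift with signal level left by the normalization is argued against by the median excess of these genes over other genes of the same level, 0.572 log2 (-0.103 to -0.048 in the other 7 groups). Passive and active SIgA raising them whatever the treatment is argued against by a median difference of -0.005 after DSS, where the untreated difference was 0.683. A preparation or hybridisation difference of these 2 arrays cannot be told apart from an effect of the group, since both arrays carry the 63.8% and no batch is named. An effect of passive and active SIgA in untreated mice alone stays open and untested.

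Genes near Pigr differed with offspring genotype: after DSS, 5 of the 200 genes nearest to Pigr on chromosome 1 had an unadjusted p under 0.01 (Ctse, Pm20d1, Snrpe, Tmem37 and Tnni1), 2.5% against 0.27% of other genes (Fisher's exact p = 0.000312, two-sided). Without the untreated group with passive and active SIgA the shares were 4% against 1.91% in untreated mice (Fisher's exact p = 0.0604) and 2% against 0.67% over both treatments (Fisher's exact p = 0.0494), so the excess was weaker there. That is consistent with DNA of the targeted cell line's strain staying linked to the Pigr allele. For the window as a whole, a stretch of genes that varies in any comparison is argued against by the dam genotype after DSS, with 1% against 1.04% (Fisher's exact p = 1). The window was not tested by dam genotype in untreated mice alone. There Ctse stood at 10.49 and 9.80 with passive SIgA and at 9.75 and 9.06 without. After DSS, Ctse stood at 9.86 in Pigr+/- and 8.75 in Pigr-/- offspring with passive SIgA, but at 9.32 and 9.17 without, so its genotype difference was not even. With DSS itself the shares were 18% against 15.06% (Fisher's exact p = 0.235). Ctse, Pm20d1, Snrpe and Tnni1 were among those 18%, so these genes also varied with DSS. An effect of the lost SIgA transport on these genes stays open, since genotype and transport go together in every group.

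Myeloid markers were higher after DSS in each SIgA group. A lower share of epithelial cells in the isolate would raise every other cell type alike. Among T cell, B cell, fibroblast, smooth muscle and endothelial lists the highest median was 0.059 log2, where neutrophil markers had 0.757. In single SIgA groups the highest of these medians was 0.229 (fibroblast, neither) where the lowest neutrophil median was 0.748. For neutrophil markers these medians go against a lower share for the lists as a whole and do not exclude it. Some members, such as Ms4a1 and Emcn, stood near the low end of the values, where a rise hardly shows. Of 22 fibroblast markers 5 rose, Vim and Dcn by more than the neutrophil median. For monocyte and macrophage markers, with 0.263 over all groups, a lower epithelial share cannot be told apart from a rise in these cells alone. Their medians of 0.428, 0.358 and 0.327 with passive and active, passive only and neither lay beside 0.224 for smooth muscle and 0.18 and 0.229 for fibroblast lists. With active SIgA only their median was 0.129, where T cell, B cell, fibroblast, smooth muscle and endothelial lists went the other way, at -0.16 to -0.089. Myeloid cells among the isolated cells may account for the rise. The median of 6 abundant myeloid transcripts was at least 0.321 in each SIgA group. Tyrobp stood at 0.98, Fcer1g at 0.99, Csf1r at 0.44, Cd68 at 0.40 and Laptm5 at 0.37, while C1qa stood at 0.01 (limma adjusted p = 0.954). Tyrobp, Fcer1g and Csf1r belong to the monocyte and macrophage list, so these values restate its rise in part and do not decide its cause. Expression of these genes by the epithelial cells themselves was not tested.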

How the results depend on the processing

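Leaving out the untreated group with passive and active SIgA, leaving out 3 arrays and the additive fit were chosen only after the result was seen. Of the comparison results under all alternatives, 270 stayed within 1.5 times the count given in the report (or kept Pigr's call) and 222 moved further. The DSS count over all groups moved further only without that group, without the 3 arrays at the low end of the first principal component and at a 1.5-fold change, and Pigr by offspring genotype (-0.88 to -0.83) and its single call after DSS held under every alternative run. Of single-gene results 7757 kept direction and call, 1236 were weaker, 53 stronger and 1 reversed. Of list results 3421 kept both, 177 were weaker, 137 stronger and 5 reversed. The causes were not tested, except that fewer arrays, fewer genes or a stricter threshold act by construction. The labels do not say that a replicate number marks anything shared. Over 28 pairs of groups the correlation of replicate differences was over 0.1 in 14 and under -0.1 in 9 (-0.301 to 0.666), so the numbers do not pair the arrays throughout, but 5 groups (all but 3 of the 8: passive and active untreated, active only after DSS, neither after DSS) correlated at 0.275 to 0.666 with one another, a shared structure the labels do not name.

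In the order passive and active, passive only, active only, neither, the moved DSS counts were as follows. Active only and neither gave 329 and 343 with limma-trend, and active only 115 with no moderation. Array weights gave 698, 68 and 547 for the last 3 groups. Quantile normalization gave 319 for active only. Without the dimmest 30% of genes, passive and active gave 750 (523 higher, 227 lower). All probe sets gave 3234, 99 and 117 for passive and active, active only and neither. At an adjusted p under 0.1 the last 3 gave 642, 362 and 383. With only the arrays compared, passive and active gave 635 and active only 33. A 1.5-fold change left 338 for DSS over all groups, leaving out the untreated group with passive and active SIgA 1210, and leaving out the 3 arrays 1107, with 67 for active only. Centring moved the direction of calls: 874 higher and 1637 lower for DSS, and 317 and 2056 with passive and active SIgA.

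For passive SIgA (all arrays, untreated, DSS) limma-trend gave 384, 803 and 25; no moderation 33 for all arrays; array weights 127 and 283 for the first 2; the replicate block 16 after DSS; centring 330, 949 and 4; quantile normalization 397 and 1049; without the dimmest genes 202 untreated and 15 after DSS. All probe sets gave 979 and 1577, a 1.5-fold change 27 and 194, an adjusted p under 0.1 552, 1304 and 17, only the arrays compared 189 untreated and 2 after DSS, no untreated group with passive and active SIgA 3, 0 and 2, without the 3 arrays 9, 0 and 4, and the additive fit 54, 0 and 3.

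For active SIgA (all arrays, untreated) no moderation gave 21 and 672, the replicate block 415 and 2326, centring 430 for all arrays, quantile normalization 111 and 635, without the dimmest genes 7 and 19, all probe sets 993 and 2530, a 1.5-fold change 23 and 551, an adjusted p under 0.1 648 and 2934, only the arrays compared 933 untreated, and each of the later alternatives 1 and 0.

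For the interactions (passive by DSS, active by DSS, passive by active, three-way) limma-trend gave 105 for active by DSS; no moderation 2, 18, 2 and 0; array weights 9 and the replicate block 35 for passive by active; centring 139, 308, 99 and 76; quantile normalization 43, 79, 51 and 58. Without the dimmest genes the counts were 0, 5, 0 and 0, with all probe sets 646, 859, 638 and 622, at an adjusted p under 0.1 74, 311, 64 and 46, with the additive fit 0 each, and without the untreated group with passive and active SIgA, or the 3 arrays, 0 for the first 3. The three-way term and the DSS effect with passive and active SIgA had no value there.

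Leaving out 1 array gave 1951 to 3290 genes for DSS, 814 to 2486, 107 to 486, 64 to 672 and 54 to 274 within its groups, 52 to 267, 157 to 714 and 0 to 4 for passive SIgA, 58 to 1043, 476 to 4718 and 1 to 1 for active SIgA, 1 to 84, 34 to 527, 4 to 60 and 3 to 65 for the interactions, and -0.873 to -0.826 for Pigr. Counts moved over 1.5 times for 0 of the 16 arrays for DSS and 15 for active SIgA by DSS.

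Reversed were Mucl2 in active SIgA by DSS (-0.055 without the untreated group with passive and active SIgA), and by camera's direction, with medians in parentheses, the neutrophil list (-0.02 without the dimmest genes) and the sterol list (-0.02 without DSS replicate 1 of passive only, up to 0.078 with another array left out) for passive SIgA after DSS, and for active SIgA after DSS the sterol list (0.057 without the same array, down to -0.041 with another left out) and the xenobiotic list (0.006 without DSS replicate 2 of passive only, -0.01 without DSS replicate 1 of neither, up to 0.097 with another left out). Dim genes near background cannot show small changes.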

Other observations

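The tests in this part, of small RNAs as a class and of single clock and sex-linked genes per array, were all chosen only after the result was seen.

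Many small nuclear, nucleolar and related RNAs stood higher without passive SIgA. Of 66 such genes on the array, 30 were called higher and 0 lower over all arrays, 95.5% stood above 0 (53.4% of other genes), and the median difference was 0.42 log2. Without the untreated group with passive and active SIgA 3 were called higher, 93.9% stood above 0 and the median was 0.36. After DSS alone the median was 0.47 with none past the threshold in limma, in untreated mice it was 0.34 with 13 higher (0.10 with 0 called by limma without that group, where 1379 of all genes had an unadjusted p under 0.05), and most also stood above 0 by offspring genotype: 83.3% after DSS (median 0.13) and 89.4% in untreated mice (0.19 with 4 higher, but 50% without that group). With DSS 1 rose and 5 fell, with a median of -0.11. Their median level per array ran from 8.83 to 9.99, and no measure of RNA recovery was available to set beside it.

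Clock genes varied between arrays of the same group and also went with dam genotype. Dbp, a clock output gene, ranged from 7.29 to 9.80 and Ciart from 6.32 to 8.91 over the 16 arrays, and the 2 DSS pools with passive SIgA only stood at 7.29 and 8.95 for Dbp. In untreated mice the group means of Nr1d2 were 9.35 and 9.72 with passive SIgA and 10.37 and 10.41 without. Arntl, another clock gene, went the other way, at 9.33 and 9.15 with and 8.87 and 8.74 without. After DSS the differences were 0.32 ± 0.13 for Nr1d2 and -0.34 ± 0.16 for Arntl, neither past the threshold. The labels give no time of day, so a difference in clock phase cannot be told apart from passive SIgA. Xist, expressed from the inactive X chromosome, ran from 11.36 to 12.58 and the Y-linked Kdm5d from 6.53 to 8.20. Whether the pools held different mixtures of the sexes was not tested, and the labels do not give them.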
